A study of Homo sapiens with 2 samples.

How the data were processed

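MicroRNA (miRNA) abundance was measured on 2 one-colour arrays, one from H460 cells given vehicle and one from H460 cells given sulforaphane, both for 48 hours. Per the labels' protocols, total RNA was isolated with TRIzol and a column kit, labelled with the Hy3 dye and hybridised to miRCURY LNA arrays, whose capture probes contain locked nucleic acids, and the second dye was not used. Each group held 1 array, so no spread between samples could be estimated, no test between the groups was possible and no p-value is given for any difference between them. The number of arrays limits the precision, and the dose of sulforaphane is not given in the sources used here.

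Per the file headers, the deposited workbook gave for each probe and array the foreground intensity, the foreground minus background intensity and a normalized value. Spot numbers, scanner, background method and software are not given in the sources used here. The normalized value deposited by the authors is a ratio: dividing the background-subtracted intensity by it gave the same factor for each of the 2661 probes with values, 111.5 on the vehicle array and 124 on the sulforaphane array. How the authors chose these factors is not given in the sources used here. A single factor per array cannot remove differences that depend on intensity. The fold change in the authors' deposited table equalled the ratio of the normalized values, sulforaphane over vehicle, for every probe to within 2.1e-14. The series value table matched the workbook by probe ID for all 2661 probes, to within 4.9e-08, and is on the same linear scale.

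The workbook named 1273 human miRNA probes, of which 21 name several miRNAs, as well as 143 viral miRNA probes, 52 spike-in probes of one set and 24 probes for other small RNAs (small nucleolar RNAs, small nuclear RNAs and 5S ribosomal RNA). A further 19 named probes, mostly an older spike-in set and negative controls, were not used here apart from a probe named for the dye. Another 1150 probes had no name in the file and stayed out of the comparison. Each miRNA probe name occurred once. The spike-in probes were recognised by their names alone, and the amounts added to each sample are not given in the sources used here. The files give no coordinates or genome build. Which miRNA genes neighbour each other was taken from the RefSeq gene table of assembly GRCh38.p14, and none of its coordinates are printed.

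The comparison was the log2 ratio of normalized intensity, sulforaphane over vehicle, with no value added before the logarithm. A human miRNA was compared where it exceeded a detection floor on both arrays. The floor was the 95th percentile of the viral miRNA probes on the same array, which was a normalized intensity of 6.44 (718 background-subtracted units) for vehicle and 5.52 (684 units) for sulforaphane. Foreground intensities at 65535, the scanner limit, were taken as saturated. There were 3 such probes on the vehicle array and 7 on the sulforaphane array, of which 1 was a named miRNA. As no test could be made, a size rule of 2-fold was used. The spread of the spike-in probes' log2 ratios served as a measure of the technical spread between probes. It holds none of the variation between cultures.

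Before the data were examined, 17 lists of miRNAs were fixed: the let-7 family, the miR-200 family, the miR-17-92 clusters, p53-responsive miRNAs, the miR-15/16 family, the miR-29 and miR-148 families, the miR-30 and miR-26 families, miRNAs raised in lung tumours, the NRF2-KEAP1 pathway, the miR-302 and miR-371 clusters, the miR-199a/214 cluster, miRNAs induced by heat or oxidative stress, lists for blood and immune cells, for mesenchymal, endothelial and muscle cells and for neuronal and liver cells, the chromosome 14q32 cluster and the chromosome 19 cluster. A list took the main arm of each miRNA, under its older name without an arm where the array used that. For lists with at least 3 detected members, the median log2 ratio was placed among 10000 random lists of the same size, matched in 10 bins of mean intensity. The percentile describes these arrays and is not a test between the groups. The floor, the size rule and the following rule for named miRNAs were also fixed before the data were examined: the 10 highest and 10 lowest ratios, the 5 brightest, up to 3 of the brightest members of each list with its most extreme member, miR-214-3p and miR-200c-3p, and the 3 highest bounds in each direction among miRNAs above the floor on only 1 array.

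The alternatives were unnormalized intensities, scaling by the median of detected miRNAs or by summed intensity, quantile and cyclic loess normalization (limma 3.58.1 in R 4.3.3), other floors, the floor added to each value before the logarithm, other size rules, list means and unmatched random lists. Scaling by the spike-in probes or by the other small RNAs, and leaving out saturated probes, were added after the data had been seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The calculation of the calls and of the list percentile was tested on simulated data: 1273 miRNA probes were drawn from the vehicle values with the spike-in spread, and 100 were changed 3-fold in each direction. The 2-fold rule called 15 of the 15 raised and 10 of the 10 lowered miRNAs that remained above the floor on both arrays, and 0 of 121 unchanged ones. A simulated list of 8 miRNAs raised by 0.5 log2 units reached the 99.9th percentile. A 3-fold change lies far past the rule, and the simulation holds neither variation between cultures nor a shift of a whole array, so it checks the calculation and not the rule.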

Results

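The data were miRNA profiles of H460 cells, a human large cell lung carcinoma line that belongs to the non-small cell group, after 48 hours with vehicle or with sulforaphane, an isothiocyanate from cruciferous vegetables that activates the antioxidant regulator NRF2. Each condition was measured on 1 array, without replicates. The median foreground intensity over all probes was 128.5 on the vehicle array and 163.5 on the sulforaphane array, and the median local background was 41 and 61 units. Of 1273 human miRNA probes, 168 (13.2%) exceeded the detection floor on both arrays, 14 did so on the vehicle array alone and 44 on the sulforaphane array alone. The normalized floor was lower on the sulforaphane array (5.52 against 6.44), and some of the 44 read under 6.44 there. Across the 168 detected miRNAs, the log2 intensities of the arrays correlated with Pearson's r = 0.954, a value across genes, which are not independent replicates.

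Several unnamed probes were brighter than any named miRNA. By the mean of both arrays, the brightest named human miRNA probe was that for miR-1260b (normalized 422 with vehicle and 528 with sulforaphane). Its sulforaphane spot was at the scanner limit, so that value is a lower bound. It was followed by miR-23b-3p (172 and 246), miR-4284 (165 and 220), miR-29a-3p (log2 ratio 0.42) and miR-22-3p (136 and 185). Probes differ in affinity, so brightness does not order miRNAs by abundance. miR-21-5p, an abundant miRNA of many carcinomas, read 93.5 with vehicle and 122 with sulforaphane.

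The main question was which miRNAs differ after sulforaphane. On the authors' normalized scale, 6 of the 168 detected miRNAs were at least 2-fold higher with sulforaphane and 2 were at least 2-fold lower, while 160 differed by less. The higher ones were miR-4324 (2.76-fold, from 11.1 to 30.6), miR-32-3p (log2 ratio 1.32, from 13.4 to 33.4), miR-943 (2.47-fold, from 17.5 to 43.3), miR-935 (2.24-fold, from 9.79 to 21.9), miRPlus-A1015, a sequence named by the array's maker (2.13-fold, from 18.2 to 38.8), and miR-3613-3p (2.11-fold, from 52.6 to 111). The lower ones were miR-937-3p (2.26-fold, log2 ratio -1.17) and miR-122-3p, the minor arm of the liver miRNA miR-122 (2.13-fold, from 14.6 to 6.83). The main arm, miR-122-5p, was under the floor on both arrays (1.74 and 1.14). The other arm of miR-32, miR-32-5p, was above the floor with sulforaphane alone (5.82 and 9.14). Both of these arms were named after their values had been seen. These counts leave out miRNAs above the floor on 1 array. With vehicle alone, 11 such miRNAs had a measured log2 ratio of -1 or lower. With sulforaphane alone, 4 had a ratio of 1 or higher. The balance of higher and lower calls thus depends on requiring both arrays. No viral probe passed the size rule among the 7 above the floor on both arrays. The floor was set from the viral probes themselves and left only these 7, too few to serve as a background for the calls.

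The scale behind these counts was not neutral. The median log2 ratio of the detected miRNAs was 0.38, with quartiles of 0.12 and 0.54, and 139 of the 168 had a ratio above 0. The 41 spike-in probes above the floor had a median log2 ratio of 0.68 ± 0.20 (SD between probes), and the 21 other small RNA probes a median of 0.25 ± 0.25. Most of these spike-in probes were brighter than the called miRNAs other than miR-3613-3p, so their spread need not hold at those intensities. Relative to the median of the detected miRNAs, 1 miRNA (miR-4324) was at least 2-fold higher and 5 were at least 2-fold lower (miR-937-3p, miR-122-3p, miR-505-5p, miR-183-5p and miR-22-5p). After each array was divided by the median of its detected miRNAs, 2 miRNAs were at least 2-fold higher and 4 at least 2-fold lower. After scaling to the spike-in probes the counts were 0 and 9. Over the 7 other scalings tried, most of which shift all miRNAs by one amount, the log2 ratio of miR-4324 ranged from 0.76 to 1.62, that of miR-3613-3p from 0.37 to 1.23, that of miR-122-3p from -1.80 to -0.94 and that of miR-937-3p from -1.88 to -1.02. Without replicates, none of these differences could be set against the variation between cultures.

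**Figure D1:**
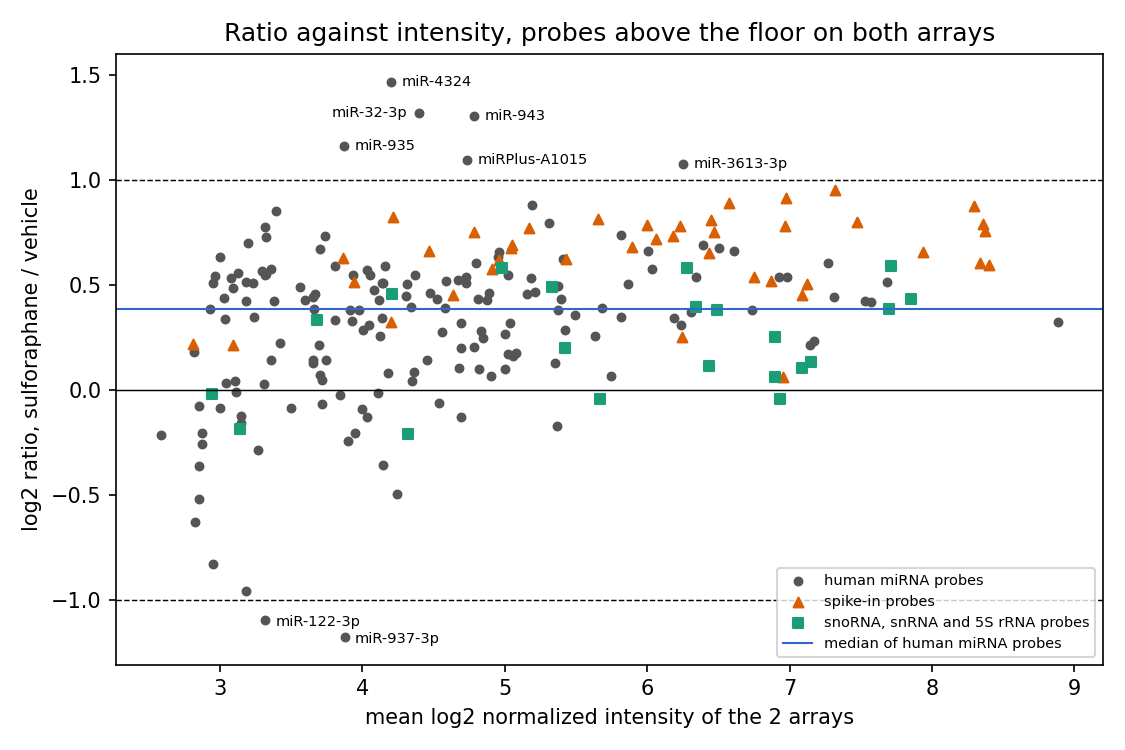
Log2 ratio of normalized intensity, sulforaphane over vehicle, against the mean log2 normalized intensity of both arrays, for probes above the floor on both. Each point is 1 probe, dashed lines mark 2-fold, and the blue line marks the median of the 168 human miRNA probes at 0.38; the 41 spike-in probes lie mostly above that line.

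Below the size rule, the next highest ratios belonged to miR-7-5p, which targets the EGF receptor (log2 ratio 0.88, from 27.0 to 49.7), miR-374c-5p (0.85), miR-19a-3p (0.79) and miR-431-5p (0.78). The next lowest belonged to miR-505-5p (-0.96, from 12.6 to 6.51), miR-183-5p (-0.83, from 10.3 to 5.81), miR-22-5p (-0.63), miR-944 (-0.52), miR-498 (-0.50), miR-335-5p (-0.36), miR-138-1-3p (-0.36) and miR-1275 (-0.29).

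Some miRNAs were above the floor on a single array, so their fold is a bound against the floor of the other array, on the authors' scale. Under spike-in scaling the bounds for higher miRNAs are smaller, and without normalization those for lower ones are. With sulforaphane, miR-301a-3p was at least 2.19-fold higher (measured 5.20 and 14.1), miR-3171 at least 2.09-fold (2.35 and 13.4) and miR-21-3p, the minor arm of miR-21, at least 1.69-fold (5.60 and 10.9). In the other direction miR-138-2-3p was at least 2.67-fold lower (14.7 and 2.59), miR-377-3p at least 2.30-fold (12.7 and 2.15) and miR-129-1-3p at least 1.70-fold (9.39 and 5.42). The main arm of miR-138, miR-138-5p, was above the floor on both arrays (log2 ratio 0.14, from 9.75 to 10.8). It was named after its value had been seen.

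The miR-17-92 cluster and its paralogs, which are MYC-activated and promote proliferation, lay mostly above the median of detected miRNAs. All 11 detected members had a ratio above 0 on the authors' scale and 9 lay above the median of detected miRNAs. None reached 2-fold. The members included miR-19a-3p (0.79), miR-93-5p (0.74, from 43.6 to 72.6), miR-20a-5p (0.69, from 66.0 to 107) and miR-106b-5p (0.68, from 72.0 to 115). The list's median log2 ratio was 0.55, which is 0.17 above that of all detected miRNAs. It was at the 98.6th percentile of intensity-matched random lists, 1 of 8 such percentiles computed. Members of clusters and their paralogs need not be independent of one another, and the random lists do not carry such links. The percentile ranged from 91.0 to 99.7 over the alternatives, and the median itself fell below 0, to -0.15, under spike-in scaling alone among the 7 scalings.

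The let-7 family, which represses RAS and MYC, lay in the middle of the profile. The 7 detected members had log2 ratios from 0.09 to 0.54 with a median of 0.39, at the 49.9th percentile. They included let-7i-5p (0.54, from 105 to 152), let-7g-5p (0.34) and let-7b-5p (0.43). The ratio of let-7g-5p was below 0 under 5 of the 7 scalings and that of let-7b-5p under 2. The family's median was below 0 under quantile, spike-in and small RNA scaling. The miR-15/16 family, which represses cyclins and BCL2, was also central: miR-16-5p (0.37), miR-15a-5p (0.38) and miR-15b-5p (0.49) gave a median of 0.38, at percentile 36.1. Its sign was opposite under these same 3 scalings and under cyclic loess.

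The miR-29 and miR-148 families, which target DNA methyltransferases, had 4 detected members with a median of 0.49 (78.0th percentile), among them miR-29b-3p (0.66), miR-148b-3p (0.52) and miR-29a-3p (0.42). The miR-30 and miR-26 families had 5, with a median of 0.53 (90.7th percentile). In that list miR-30b-5p (0.73), miR-26b-5p (0.53) and miR-30c-5p (0.46) lay above the median of detected miRNAs and miR-30a-5p (0.28) below it. The list of miRNAs induced by heat or oxidative stress had 8 detected members with a median of 0.53 (84.5th percentile), including miR-23a-3p (0.66), miR-24-3p (0.54) and miR-23b-3p (0.52). The medians of these 3 lists were below 0 under spike-in scaling alone. Some members turned under more of the 7 scalings: the ratio of miR-30a-5p was below 0 under 6, miR-29a-3p under 3 and miR-30c-5p under 2.

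MiRNAs raised in lung tumours split. Of 7 detected members, 4 had a ratio above 0 and 3 below it. miR-222-3p (0.57, from 53.8 to 80.1) and miR-21-5p (0.38) were among the former, and miR-183-5p (-0.83) and miR-31-5p (-0.06, from 23.7 to 22.7) among the latter. The ratio of miR-31-5p was above 0 without normalization. The list median of 0.38 lay at the 51.4th percentile, and it was below 0 under quantile, cyclic loess, spike-in and small RNA scaling.

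Lists with fewer than 3 detected members have values only. The NRF2-KEAP1 list had 2: miR-93-5p (0.74) and miR-27a-3p (0.60, from 22.6 to 34.3). Another of its members, miR-206, was above the floor on the vehicle array alone (6.61 and 1.80). It was at least 1.20-fold lower on the authors' scale. Of the p53-responsive miRNAs, miR-34a-5p read 23.2 with vehicle and 28.9 with sulforaphane (0.32), and miR-107 read 7.20 and 11.7 (0.70). miR-302a-3p (0.34) was the 1 detected member of the stem-cell clusters. The chromosome 19 cluster had 2 detected members, miR-498 (-0.50) and miR-519e-3p (-0.08). The sign of miR-34a-5p and of miR-302a-3p was opposite under 5 of the 7 scalings, and that of miR-107, miR-27a-3p and miR-519e-3p under 1.

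Neither miR-200c-3p nor miR-214-3p was above the floor on either array. miR-200c-3p, an epithelial miRNA, read 3.97 with vehicle and 3.96 with sulforaphane, and no member of the miR-200 family was detected. miR-214-3p read 0.933 and 1.31, and no member of its cluster with miR-199a was detected. A difference in either was not detectable at these signals. Markers of other cells were mostly under the floor too. None of 9 blood and immune miRNAs was above it on either array, and the brightest with vehicle was miR-150-5p at 2.02. Among 12 mesenchymal, endothelial and muscle miRNAs, 1 was above the floor on the vehicle array (miR-206) and 1 on the sulforaphane array (miR-126-3p). Of 7 neuronal and liver miRNAs, 0 were above it with vehicle and 2 with sulforaphane. These were miR-9-5p (5.78 and 6.46) and miR-128 (3.91 and 5.52), and the normalized floor was lower with sulforaphane. miR-126-3p, miR-206, miR-150-5p, miR-9-5p and miR-128 were named after their values had been seen.

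For the imprinted cluster at chromosome 14q32 the direction depended on the floor. The 3 members of its list detected on both arrays were miR-431-5p (0.78), miR-299-5p (0.73) and miR-668 (-0.02, above 0 without normalization). Their median was 0.73, at the 98.5th percentile. A genomic neighbour of miR-299-5p outside the list, miR-495-5p, was also detected (0.07). The other arm of miR-299, miR-299-3p, also outside the list, was above the floor with vehicle alone (7.10 and 1.60). It was at least 1.29-fold lower, opposite to miR-299-5p. Both miR-495-5p and miR-299-3p were named after their values had been seen. With the floor lowered to the median of all probes, 13 members were included, 10 of them had a ratio below 0 on the authors' scale, and the median was -0.32, at the 0.38th percentile. Only 3 of the 13 were above the viral probes' floor on both arrays, so the ratios of the others are not measured folds. Among those others, miR-377-3p was above that floor on the vehicle array alone and at least 2.30-fold lower on the authors' scale. Requiring both arrays thus left out a member that was lower.

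**Figure D2:**
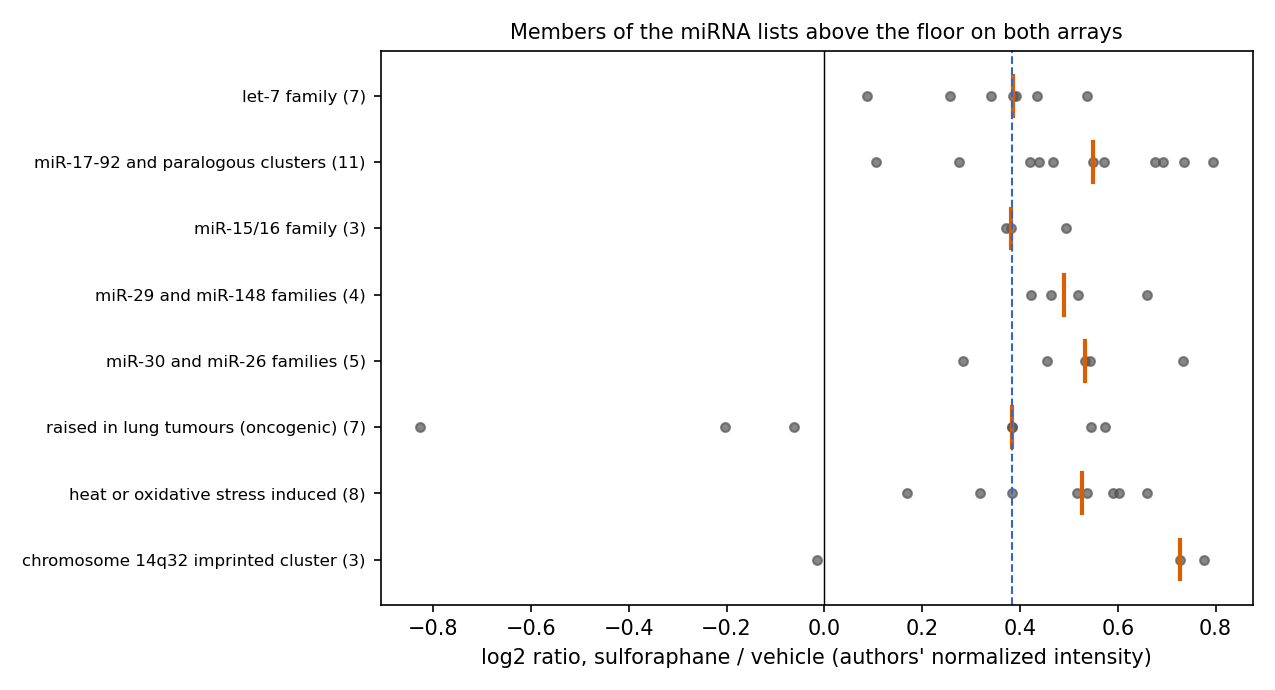
Log2 ratio of normalized intensity, sulforaphane over vehicle, for the members of each miRNA list above the floor on both arrays, with their number in brackets. Points are single miRNAs, orange bars list medians and the dashed line the median of all 168 detected miRNAs (0.38); the miR-17-92 list has its median at 0.55 and the let-7 list at 0.39, both below 0 under spike-in scaling.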

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

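The tests of sample RNA against spike-in, of a loss limited to miRNAs and of muscle RNA were chosen after the values had been seen. All results here concern probes that the comparison did not use or that were above the floor on 1 array, and none has a replicate.

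The spike-in probes, which carry no information on the cells, were brighter on the sulforaphane array, with a median log2 ratio of 0.68 on the authors' scale, against 0.38 for detected miRNAs and 0.25 for the other small RNAs. A match on intensity did not remove this gap: against the 20 miRNAs nearest in intensity, the 41 spike-in probes were still 0.19 higher (bootstrap 95% interval 0.13 to 0.25). The nearest miRNAs of the brightest spike-in probes were mostly dimmer, and miRNA ratios rose with intensity (Spearman correlation 0.26). The match was thus incomplete at that end, so an intensity-dependent response is not excluded. The interval covers probes of 1 pair of arrays. The small RNAs lay 0.13 below the miRNAs (log2 difference -0.13, interval -0.32 to 0.05). A loss limited to miRNAs would place them 0.29 above. The small RNAs were 0.42 below the spike-in probes (-0.42, interval -0.62 to -0.24), without matching on intensity. Less sample RNA, or more spike-in, on the sulforaphane array would give such a gap. That criterion and the one for a loss limited to miRNAs were set once the medians were known, so they decide nothing. Without normalization the detected miRNAs were also brighter on the sulforaphane array, with a median log2 ratio of 0.54. Whether the amounts differed at all, and whether by sulforaphane or by handling, stays open, since there was 1 array per condition.

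A set of 11 miRNA probes was above the floor on the vehicle array alone and had a measured log2 ratio of -1 or lower, with 737 to 1640 background-subtracted units against 122 to 480. It included miR-138-2-3p (at least 2.67-fold lower against the floor, on the authors' scale), miR-377-3p (at least 2.30-fold), miR-3123 (at least 1.41-fold), miR-3658 (at least 1.27-fold) and the muscle miRNAs miR-208b (at least 1.43-fold) and miR-206 (at least 1.20-fold). A further 10 unnamed probes did the same. In the opposite direction there were 4 named and 11 unnamed probes. A stain over the spots and their surroundings is argued against, because the local background of the 11 probes on the vehicle array had a median of 39.5 units, at the 5.78th percentile of random sets. Muscle RNA in the vehicle sample should also bring miR-1, miR-133a and miR-133b. The brightest of these 3 read 0.731 there, under the floor of 6.44. That criterion was set after the values had been seen, so it settles nothing. Damage within single spots, cross-hybridisation and a response to sulforaphane stay open and were not tested.

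Among the unnamed probes, 184 were above the floor on both arrays, 11 of them at least 2-fold higher with sulforaphane and 4 at least 2-fold lower. The highest log2 ratio among them was 1.74 (probe 148122, 3.33-fold), above that of any named miRNA detected on both arrays. The lowest among them was -1.42 (probe 146170). On the same scale, 6 of the 168 detected miRNAs were at least 2-fold higher and 2 at least 2-fold lower. The size rule was thus passed no more often by named miRNAs than by unnamed probes. The SD of the log2 ratios was 0.50 for the unnamed probes and 0.39 for the detected miRNAs.

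The probe named for the Hy3 dye had a log2 ratio of 1.44, from 24.6 to 66.8. A probe for a herpes simplex virus miRNA, hsv1-miR-H4-3p, read 108 with vehicle and 151 with sulforaphane, a log2 ratio of 0.48. Another viral probe, kshv-miR-K12-12-5p, read 23.0 and 25.4, within the range of the called miRNAs. If the cells carry no such virus, a signal above the floor need not come from the miRNA a probe is named for. The source of these signals was not tested.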

How the results depend on the processing

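No paired analysis was possible because each group held 1 array, and no replicate could be left out. The counts of miRNAs at least 2-fold higher and lower (6 and 2) depended on both the scaling and the floor. They were 2 and 4 with the median of detected miRNAs, 1 and 4 with quantile, summed-intensity and cyclic loess normalization, 0 and 9 with spike-in scaling, 1 and 5 with small RNA scaling, and 8 and 1 without normalization. The median log2 ratio of detected miRNAs (0.38) became 0.075, 0.025, 0.039 and -0.0021 with median, quantile, summed-intensity and cyclic loess scaling, -0.32 with spike-in scaling and -0.011 with small RNA scaling. Spike-in and small RNA scaling, leaving out saturated probes, and setting list medians against the median of detected miRNAs in place of 0, were chosen after seeing the data. Of the 8 called miRNAs, 4 were shared with the calls under the median, 3 each under quantile, summed-intensity, cyclic loess and small RNA scaling, and 2 under spike-in scaling. With floors at the 99th percentile of the viral probes, the median of all probes and none, the counts were 1 and 0 (of 67 miRNAs), 20 and 35 (of 556) and 133 and 63 (of 1273). The miRNA still called at the 99th-percentile floor was miR-3613-3p. The counts were 2 and 0 with the floor added before the logarithm, 27 and 5 at 1.5-fold, and 0 and 0 at 3-fold. List medians relative to all detected miRNAs are the same under any scaling by one factor per array. Over all alternatives they were above 0 for the miR-17-92 list (0.12 to 0.28) and the lists of miR-29 and miR-148, miR-30 and miR-26, and stress-induced miRNAs. They took either sign for let-7 (-0.03 to 0.12), miR-15/16 (-0.10 to 0.11) and miRNAs raised in lung tumours (-0.20 to 0.06). The chromosome 14q32 list went from 0.34 to 0.15 with the floor added, to -0.59 with the floor at the median of all probes (13 members) and to -0.26 without a floor (40 members), and had no member with the 99th-percentile floor. The cause of these changes was not tested, beyond the number of miRNAs that each floor admits. The list percentiles ranged from 39.3 to 57.5 for let-7, 27.0 to 61.8 for miR-15/16, 61.0 to 88.8 for miR-29 and miR-148, 67.6 to 93.9 for miR-30 and miR-26, 22.2 to 53.3 for miRNAs raised in lung tumours and 72.7 to 94.6 for those induced by stress. The series value table, the brightest probe of each name (each miRNA name occurred once) and leaving out saturated probes changed no count. Signal over background limits the rest: 1105 human miRNA probes were under the floor on at least 1 array.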

Other observations

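The miRNAs named here, the wider gene matching in the test of neighbouring miRNAs and the split of the chromosome 14q32 list by the floor were chosen after the results had been seen. The miR-320 family ran from higher to lower across its members: miR-320a (log2 ratio 0.46), miR-320b (0.21), miR-320c (0.07), miR-320d (-0.09) and miR-320e (-0.24), of which only miR-320a lay above the median of detected miRNAs. The miR-374 family lay above that median with miR-374a-5p (0.45), miR-374b-5p (0.52) and miR-374c-5p (0.85). Within the let-7e locus, miR-125a-5p (0.25), let-7e-5p (0.39) and miR-99b-5p (0.42) were close to one another, as were miR-221-3p (0.55) and miR-222-3p (0.57). Other neighbours lay apart, such as miR-92a-3p (0.11) and miR-19a-3p (0.79), miR-495-5p (0.07) and miR-299-5p (0.73), and miR-183-5p (-0.83) and miR-182-5p (-0.20). These ratios are on the authors' scale, and a ratio under 0.68 there lies below that of the spike-in probes.

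A hypothesis was that miRNAs processed from one primary transcript have similar ratios. Names were matched to genes of the GRCh38.p14 RefSeq table (156 of 160 names), and pairs with different numbers and genes within 10 kb were compared. A first matching left out genes whose copies are numbered after a dash; over its 43 pairs the mean absolute difference of log2 ratios was 0.27, against 0.39 after shuffling ratios within intensity bins (one-sided permutation p = 0.0546). The matching was widened after that result had been seen, and 49 pairs then gave 0.24 against 0.38 (permutation p = 0.0214). Without pairs inside the miR-17-92 clusters, the wider matching gave 0.22 against 0.38 over 19 pairs (permutation p = 0.0214) and the first one 0.28 against 0.43 over 13 pairs (permutation p = 0.0982). Both calls thus depended on a choice made after a result was known, so the hypothesis was left undecided, as was whether those clusters alone account for the difference. Pairs that share a miRNA are not independent.

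The same idea was tested on the arms of single precursors. Over 9 precursors with both arms detected, the mean absolute difference was 0.55, against 0.47 after shuffling (one-sided permutation test, p = 0.741). By the criterion written beforehand, a difference not below 95% of the shufflings counted against a shared transcript. That criterion was too weak and was dropped after the result was seen, since a p-value above a threshold over 9 pairs excludes nothing. The arms of miR-183 (5p -0.83, 3p 0.35), miR-22 (5p -0.63, 3p 0.44) and miR-335 (5p -0.36, 3p 0.54) had ratios of opposite sign on the authors' scale. Their 5p arms read 5.81, 5.71 and 6.38 with sulforaphane, near the floor of 5.52 there.

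With the floor at the median of all probes, 10 of the 13 members of the chromosome 14q32 list were under the viral probes' floor on at least 1 array, and their median log2 ratio was -0.45. The 378 other miRNA probes in that range had a median of 0.22 on the authors' scale. Signals under the floor are not measured folds, so these values decide between no explanations.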
